A study of Homo sapiens with 22 samples.

How the data were processed

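RNA abundance was measured by RNA sequencing in prostaspheres, free-floating spheres of stem and progenitor cells enriched from RWPE-1, an immortalized line of human prostate epithelial cells. Spheres were grown without attachment for 7 days with 1 of 6 metals or with none. Per the labels' protocols, total RNA was extracted with a kit that also keeps small RNA, and libraries were made with standard Illumina steps. The deposited table holds whole-number counts of reads per gene, not normalized, for 26347 genes in 22 libraries. Per the submitters' processing notes, bcl2fastq, TopHat and edgeR were used with the human genome build hg19, with no versions named. The read counter, the gene annotation, and whether counting used strand are not given in the sources used here. Reads of near-identical family members, pseudogenes and antisense partners therefore cannot be told apart, which bears on metallothioneins, the SPRR2 and LCE families and FTH1. No coordinates are given, because the annotation used for names is on another build.

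Gene IDs in the table are numeric and were read as NCBI gene IDs. Of these, 26204 matched a current NCBI symbol and hold 99.9% of all counts, and 143 did not match. No count was found in any library for 3744 genes. Total counts ran from 18335264 to 33596866 per library. In a library, a count of 0 allows up to 3 counts, and such floors cover counting error only. None of the 13 mitochondrially encoded mRNAs is among the IDs, so that list was not tested.

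Groups and replicate numbers come from the treatment labels: 4 control libraries, 3 each for inorganic arsenic (iAs), Cd, Cr and Cu, 4 for Ti and 2 for Pb. The doses disagree between 2 places. The sample labels give 5 µM for iAs and Cd, 10 µM for Ti and Cu, and 1 µM for Cr and Pb. The series text gives 5 µM for iAs, 10 µM for Cr, and 1 µM for Cd, Cu, Ti and Pb. Only iAs and Pb have the same dose in both. Nothing in the labels says whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Over the 25 pairs of libraries within a group, the chi-square per degree of freedom of their counts ran from 48.0 to 294, far above sampling noise, so every library was kept as a replicate.

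Each metal was compared with control by edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling. Genes with too few reads were removed with filterByExpr, which left 16349 genes. All 22 libraries entered 1 fit of group means, and p-values were adjusted by Benjamini-Hochberg at 0.05. Arsenic was also compared with Cd, and every other pair of metals was tested in the same fit. CPM values are counts relative to the TMM-scaled library size. Standard errors of log2 fold changes are those implied by the F test.

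The design, 29 gene lists, the named-gene rule and the alternatives were fixed before the data were examined, apart from the exceptions named here. The 26 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and adjusted over lists within a comparison. The endothelial and neuroendocrine lists had too few tested members (3 and 4). A list score is the mean log2 CPM of its members (prior count 2) relative to the control mean. The rule took, for each metal, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a symbol and a mean log2 CPM of at least 1, with all metal libraries on that side of the control mean. It also took up to 4 members of each list with the smallest adjusted p, and 12 sentinel genes of metal, oxidative and epithelial state, called or not. For iAs against Cd it took 6 genes in each direction for which every iAs library lay beyond every Cd library, and the sentinels. KRT1, KRT10, FLG and IVL in iAs, CES1 and PLIN2 in Pb, and MT1E, EEF1A2, RESF1, CLDN12, SEL1L3, IGFL1, HPGD and PTMS in Cd were chosen after their values were seen. LINC00324 and MYH7, named in the closing sections, were also chosen outside the rule.

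Whether replicate numbers pair the libraries was checked by correlating deviations from group means over genes. Same-numbered libraries of a metal and control correlated at 0.313 to 0.525 for Cd, 0.409 to 0.542 for Cr, 0.367 to 0.565 for Cu and 0.29 to 0.586 for Ti, so in these comparisons the numbers pair the libraries. The pairing comes from the numbers in the treatment labels. Differences between numbers are called differences between runs or culture runs below, but the labels do not say that a number marks a culture run. Alternatives were DESeq2's size factors, DESeq2 1.42.0 itself, no filter, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. A pair of settings without iAs 2 and Pb 2, the fold bounds without each library and the simulated and split-control shares of arsenic genes in other metals were added after seeing the data.

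The pipeline was tested on simulated counts for the 16349 genes, with run differences kept and 200 genes changed. The changed genes were drawn from those with a mean count over 50 per library, so recovery of genes with fewer reads was not tested. For the arsenic comparison, the fit of group means recovered 50% of genes changed 2-fold and 89% of genes changed 4-fold, with 0 false calls. For the Cr comparison (16348 genes) it recovered 32% and 84%, for Ti 60% and 87%, and for Pb 37% and 85%. With the replicate number as a block, recovery was 82% and 97% for arsenic and 83% and 100% for Cr, with 9 false calls in each. The counts were drawn from the fit with this block, so every simulated library followed its replicate number. In the data iAs 2 and Pb 2 did not, so recovery with the block may be too favourable for arsenic and Pb. False calls with the block ran from 5 in Cd and Pb to 11 in Cu. Figures were drawn with matplotlib 3.10.9.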

Results

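The data are gene-level read counts of 22 libraries of RWPE-1 prostaspheres, grown for 7 days with inorganic arsenic (iAs, n = 3), Cd (n = 3), Cr (n = 3), Cu (n = 3), Ti (n = 4), Pb (n = 2) or no metal (n = 4). Depth ran from 18335264 to 33596866 counts per library. The number of genes with at least 1 count ran from 14758 in iAs 4, with 31468284 counts, to 18538 in control 1. Doses by sample label were 5 µM for iAs and Cd, 10 µM for Cu and Ti, and 1 µM for Cr and Pb, and the series text gives other doses for Cd, Cr, Cu and Ti. Of the 22 libraries, 20 resembled those of their own replicate number in other groups most, all but iAs 2 and Pb 2. The number-4 library of each group had the lowest KRT1 and the highest NF-kB cytokine score of its group.

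The first question was which genes arsenic changes in prostaspheres. Genes of squamous differentiation, the program by which stratified epithelium makes its tough outer layers, fell. Of the 28 list members, 16 were lower in iAs, none was higher and 12 did not pass, and 20 passed when adjusted over the list alone. KRT1 (gene ID 3848), a keratin of suprabasal cells, went from 12000 ± 6250 CPM in control (SD, n = 4) to 326 ± 194 CPM (SD, n = 3), a log2 fold change of -5.20 ± 0.94 (SE; adjusted p = 0.00477). Its partner KRT10, the cornified envelope precursor IVL and the filament-bundling protein FLG fell, with log2 fold changes of -3.05, -4.28 and -7.56. SBSN went from 1490 ± 734 to 74.8 ± 16.5 CPM (log2 fold change -4.31 ± 0.65, adjusted p = 0.00159), and SPRR2A fell by 2.53 on the log2 scale. Camera at the preset correlation called the list (median log2 fold change -2.82, adjusted p = 4.62e-28), with adjusted p = 0.132 with an estimated correlation. KRT10 did not pass without control 1, 2 or 3, iAs 2 or iAs 4 (adjusted p of 0.0524 to 0.13), nor IVL without iAs 4 (adjusted p = 0.0517). The log2 fold change of KRT10 was -3.86 without iAs 1, and those of FLG and SPRR2A were -8.32 and -3.13 without iAs 2.

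Several genes were almost without reads in iAs. LORICRIN, the main protein of the cornified envelope, had 8 counts in the 3 iAs libraries together against 18703 in the 4 controls. The fatty acid omega-hydroxylase CYP4F22 had 3 against 5823, the squamous list member CRNN 3 against 2898, AADACL2 2 against 3669 and C5orf46 1 against 1673. LCE1F and the ceramidase ACER1 had 0 counts in iAs, which makes them at least 357-fold and 230-fold lower, taking 3 counts over the group as the floor. These bounds were 183-fold and 179-fold without control 3, and 199-fold and 128-fold without iAs 4. Control 3 also weighed on LORICRIN and CRNN, whose control means of 225 and 33.7 CPM were 109 and 21.8 CPM without it. The luminal markers CD24 and ACP3 fell (log2 fold changes -1.93 and -2.94), 2 of 13 members of the luminal list, which was not called (median -0.05, adjusted p = 0.353). KLF4, a transcription factor of epithelial differentiation, and NES fell (log2 fold changes -2.06 and -3.41), 2 of 20 members of the stem and progenitor list, which was not called (median -0.27, adjusted p = 0.197). CD24 and ACP3 did not pass without any of control 1, control 3 or the 3 iAs libraries (adjusted p of 0.0534 to 0.132), NES without control 1, control 3, iAs 1 or iAs 4 (0.0606 to 0.0838), nor KLF4 without iAs 4 (0.0587). The log2 fold change of ACP3 was -3.64 and that of NES -5.24 without iAs 2, and that of NES -2.81 without iAs 4. The basal keratin KRT5 was at 10700 ± 3060 CPM against 9440 ± 1640 in control (log2 fold change 0.18 ± 0.21, adjusted p = 0.719), with no change called. TP63, the basal cell regulator, and the proliferation marker MKI67 were not called either (log2 fold change -0.33 ± 0.33 and -0.05 ± 0.26). The direction of KRT5 turned without iAs 2 (-0.05) and that of MKI67 without control 1 (0.02) or control 2 (0.08).

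Targets of NRF2, the regulator of antioxidant genes, rose in iAs: 12 of 32 were higher and none lower, and 21 passed adjusted over the list alone. Camera called the list (median log2 fold change 1.06, adjusted p = 6.63e-22), with adjusted p = 0.132 with an estimated correlation. HMOX1 (gene ID 3162), which degrades heme, went from 59.4 ± 12.5 to 600 ± 322 CPM (log2 fold change 3.34 ± 0.51, adjusted p = 0.00159). The efflux pump ABCC2 went from 2.38 ± 1.54 to 77.7 ± 79.5 CPM (log2 fold change 5.01 ± 0.74, adjusted p = 0.00159), and its log2 fold change was 3.72 without iAs 1 (adjusted p = 0.00918). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 2.28 on the log2 scale, TXNRD1 by 1.31, SQSTM1 by 1.27, NQO1 by 1.10 and UGDH by 1.02. The ferritin subunits FTH1 and FTL rose by 2.61 and 1.65 and the mitochondrial iron importer SLC25A37 by 0.65, 3 of 14 members of the iron handling list. Reads of FTH1 may be shared with its pseudogenes. Other genes with large rises were DHRS2 (4.49), HCLS1 (3.12), the carboxylesterase CES1 (2.77) and PANX2 (2.67). Some of these did not pass without 1 library: SLC25A37 without any one of the 7 (adjusted p of 0.0513 to 0.15), PANX2 without any but control 4 (0.0778 to 0.137), SQSTM1 without control 1, 2 or 3, iAs 1 or iAs 4 (0.0605 to 0.0768), NQO1 without control 2 or iAs 2 (0.0539 and 0.112), FTH1 without control 2 or 3 (0.0524 and 0.0614), CES1 without control 1 or iAs 1 (0.0613 and 0.0637), TXNRD1 without iAs 2 (0.0603) and DHRS2 without iAs 1 (0.0614, log2 fold change 2.94). Log2 fold changes were higher for DHRS2 without control 1 (5.29), CES1 without control 3 (3.42) and PANX2 without control 4 (4.01).

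Single members of other lists passed in iAs as well. In the interferon list 2 of 24 members were higher, among them IFIT2 by 1.48 on the log2 scale, and adjusted over the list alone 9 were higher and 1 lower. WARS1 and GDF15 of the ATF4 stress list rose by 0.69 and 1.13, the death receptor TNFRSF10B by 0.71 and the chaperone DNAJB4 by 1.08. E2F1 of the DNA replication list and PMVK of cholesterol synthesis fell (log2 fold changes -0.63 and -1.11). Of these named genes, TNFRSF10B alone passed without each library in turn. IFIT2 failed without any library but control 4 (adjusted p of 0.061 to 0.195), GDF15 without any but control 3 (0.079 to 0.134), DNAJB4 without control 1, 2 or 3, iAs 2 or iAs 4 (0.0719 to 0.104), PMVK without control 1 or 3, iAs 1 or iAs 2 (0.0502 to 0.0791), E2F1 without control 3 or iAs 4 (0.0508 and 0.0739) and WARS1 without iAs 2 (0.0549). None of the 9 metallothioneins passed, and MT1X and MT2A had log2 fold changes of 0.75 ± 0.46 and 0.95 ± 0.62.

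By edgeR's quasi-likelihood test, 596 of 16349 genes differed between iAs and control, 164 higher and 432 lower. Further lists called by camera at the preset correlation were interferon (median 0.71, adjusted p = 2.3e-05), NF-kB cytokines (1.00, 9.11e-05), ribosomal proteins (-0.34, 6.13e-05), ATF4 stress (0.30, 0.00913), iron handling (0.36, 0.0135), metallothioneins (1.13, 0.0155), glycolysis and hypoxia (0.20, 0.0274), mesenchymal genes (0.39, 0.0274) and mitotic genes (0.14, 0.0318), and none held with an estimated correlation (adjusted p of 0.217 to 0.833). The ATF4 and iron lists were not called without control 1 (adjusted p = 0.0572 for each), ribosomal proteins without iAs 1 (0.262) and metallothioneins without iAs 4 (0.0532). Within replicate numbers 1, 2 and 4, the squamous list mean of iAs minus control was -3.72, -2.08 and -3.71 on the log2 scale, and the NRF2 list mean was 1.62, 1.66 and 0.50. The list means within these numbers were 1.24, 0.48 and -0.01 for interferon, 1.82, 2.35 and 0.14 for NF-kB cytokines and -0.46, -0.18 and -0.10 for ribosomal proteins. They were 0.48, -0.06 and 0.30 for ATF4 stress, 0.75, 0.38 and 0.15 for iron handling and 1.00, 0.64 and 0.78 for metallothioneins. Signs of the mean also differed between numbers for glycolysis and hypoxia (0.54, 0.19 and -0.12), mesenchymal genes (0.46, 0.60 and -0.38) and mitotic genes (-0.23, 0.26 and 0.14), while the medians of the first 2 lists in number 4 were 0.01 and 0.26. The NF-kB median was 1.92 without control 4. Deviations of iAs 2 and control 2 from their group means correlated at -0.0861, so differences within number 2 may also hold a run difference. The count of 596 fell to 267 without control 3, 288 without iAs 2 and 298 without iAs 4, and was 306 with only the 2 groups in the fit, 213 without iAs 2 and Pb 2, and 1194 by DESeq2.

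**Figure D1:**
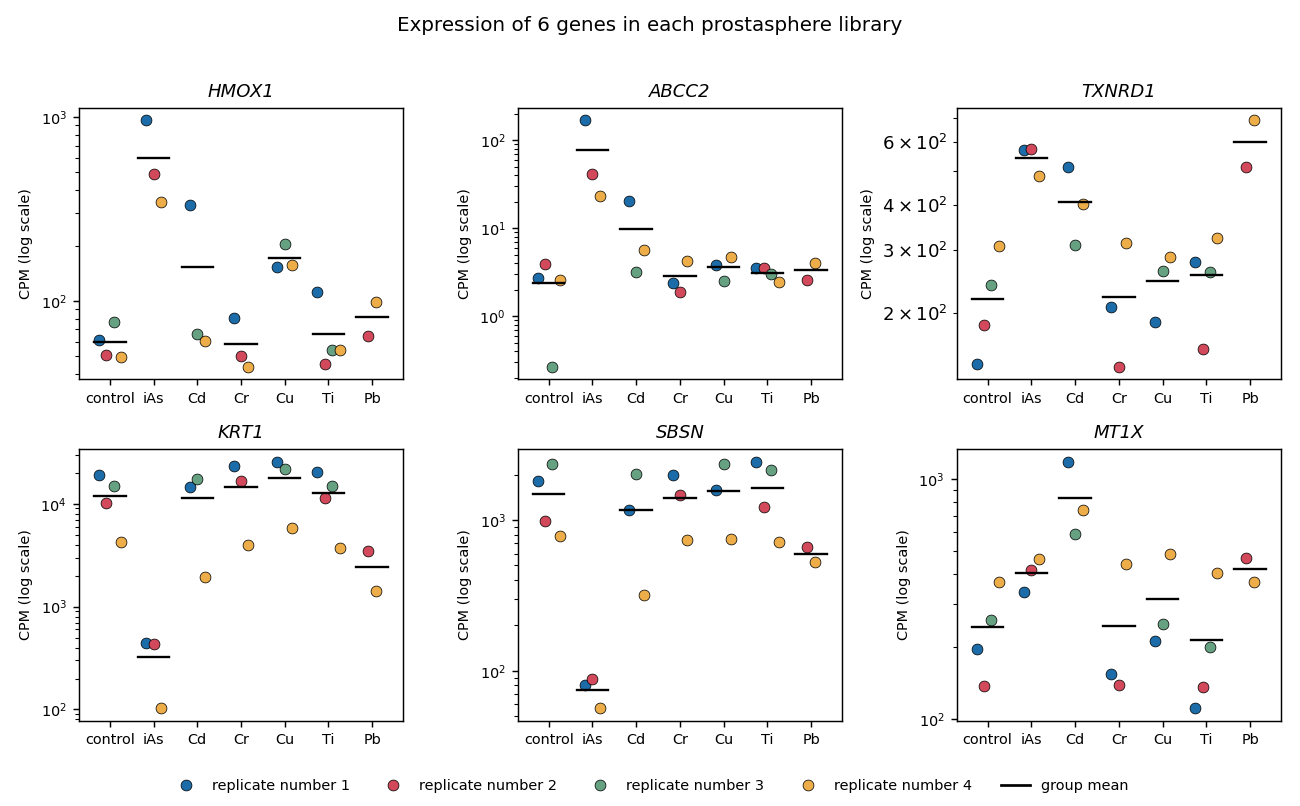
CPM (log axis) of 6 genes in each library, by group, with colour for replicate number and a bar for the group mean. In iAs, HMOX1 and ABCC2 lie above and KRT1 and SBSN below all control libraries, and MT1X is highest in Cd at a mean of 835 CPM.

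The second comparison asked what Cd changes. The genes that rose were metallothioneins, small proteins that bind zinc, copper and cadmium. MT1G (gene ID 4495) went from 0.996 ± 0.683 CPM in control (SD, n = 4) to 154 ± 204 CPM (SD, n = 3), a log2 fold change of 7.24 ± 0.99 (SE; adjusted p = 0.0097). MT1M (gene ID 4499) and MT1F (gene ID 4494) rose by 7.65 ± 1.24 and 4.83 ± 0.76 (adjusted p = 0.0336 and 0.0328). These 3 were the only genes called by edgeR's quasi-likelihood test, all higher, with 293 genes at an unadjusted p under 0.05 and 6 genes called by DESeq2. Of the 9 tested metallothioneins 8 passed when adjusted over the list alone. The Cd libraries differed widely, with MT1G at 389 CPM in Cd 1 against 18.2 in Cd 3 and 53.7 in Cd 4. MT1H had 437 counts in the Cd libraries against 3 in controls. Without Cd 1 the log2 fold changes of MT1G, MT1M and MT1F were 5.15, 5.40 and 3.12, none called. The log2 fold change of MT1M was 8.36 without control 4 (adjusted p = 0.111). MT1H passed without Cd 3 (adjusted p = 0.0387).

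With the replicate number as a block, 15 genes passed, 13 higher and 2 lower, among them the 3 above. They included MT1H, and MT1E, MT1X, MT2A and the zinc exporter SLC30A1 with blocked log2 fold changes of 3.12, 1.85, 2.57 and 1.31. The others were EEF1A2, RESF1, CLDN12, SEL1L3 and IGFL1, which were higher, and HPGD and PTMS, which were lower. In the fit of group means MT2A was at 2060 ± 873 against 413 ± 257 CPM and SLC30A1 at 127 ± 69.8 against 45.9 ± 8.66 CPM, neither called (adjusted p = 1 and 0.923). RESF1 passed there without Cd 4 (adjusted p = 0.0353). The protease CTSL was at 166 ± 49.5 against 87.6 ± 13.6 CPM (adjusted p = 0.322).

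Camera called metallothioneins in Cd (median log2 fold change 3.58, adjusted p = 1.53e-42) and zinc transporters (median 0.23, adjusted p = 4.9e-05), and both held with an estimated correlation (adjusted p = 0.000656 and 0.00715). NRF2 targets were also called (median 0.40, adjusted p = 2.47e-13), but not with an estimated correlation (adjusted p = 0.275), and 0 of 32 members passed. Within numbers 1, 3 and 4 the NRF2 list mean of Cd minus control was 1.17, 0.10 and 0.06, with 30, 15 and 16 of the 32 members above control. HMOX1 was at 153 ± 157 CPM (log2 fold change 1.37 ± 0.48), TXNRD1 at 409 ± 101, GCLM at 54.5 ± 26.9, MAFG at 165 ± 16.7 and ABCC2 at 9.79 ± 9.40 CPM, none called. HMOX1 was at 334 CPM in Cd 1, 65.6 in Cd 3 and 60.3 in Cd 4, against 61.3, 76.3 and 49.6 in the controls of those numbers. Without Cd 1 the log2 fold changes of HMOX1 and ABCC2 were 0.08 and 0.87. Iron handling, heat shock, autophagy and NF-kB cytokine lists were also called higher by camera at the preset correlation (medians of 0.0438 to 0.38). None of them held with an estimated correlation (adjusted p of 0.371 to 0.823) or with the replicate block (0.0877 to 0.244). The 5 lists called lower at the preset correlation included ribosomal proteins (median -0.29), the squamous list (-0.27) and DNA replication (-0.17), with adjusted p = 0.552, 0.616 and 0.552 with an estimated correlation. The squamous list was at 0.16 without Cd 4 and not called without control 3 (adjusted p = 0.0699), while within numbers 1, 3 and 4 its mean in Cd minus control was -0.76, -0.26 and -1.22. With the replicate block its median was -0.59 (adjusted p = 2.63e-12, and adjusted p = 0.39 with an estimated correlation). DNA replication was not called without Cd 3 (adjusted p = 0.41), and within these numbers its mean was -0.23, -0.15 and 0.04 and that of ribosomal proteins -0.15, -0.36 and -0.42. SPRR3 was at 24.9 ± 13.3 against 84.4 ± 24.5 CPM, and KRT5, TP63 and MKI67 had log2 fold changes of -0.07 ± 0.21, -0.14 ± 0.33 and -0.08 ± 0.26, none called. These 3 log2 fold changes turned above 0 without control 1 (KRT5 0.03, TP63 0.02), control 2 (TP63 0.05, MKI67 0.07) or Cd 3 (TP63 0.03, MKI67 0.18). Within replicate numbers 1, 3 and 4, the metallothionein list mean of Cd minus control was 5.54, 3.07 and 2.66, and that of zinc transporters 0.47, 0.30 and 0.40. The metallothionein median was 2.75 without Cd 1 and 4.66 without control 2. The count of 3 became 0 without Cd 1, without control 1, 2 or 4, and with only the 2 groups in the fit, and 1 without control 3 or without iAs 2 and Pb 2.

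**Figure D2:**
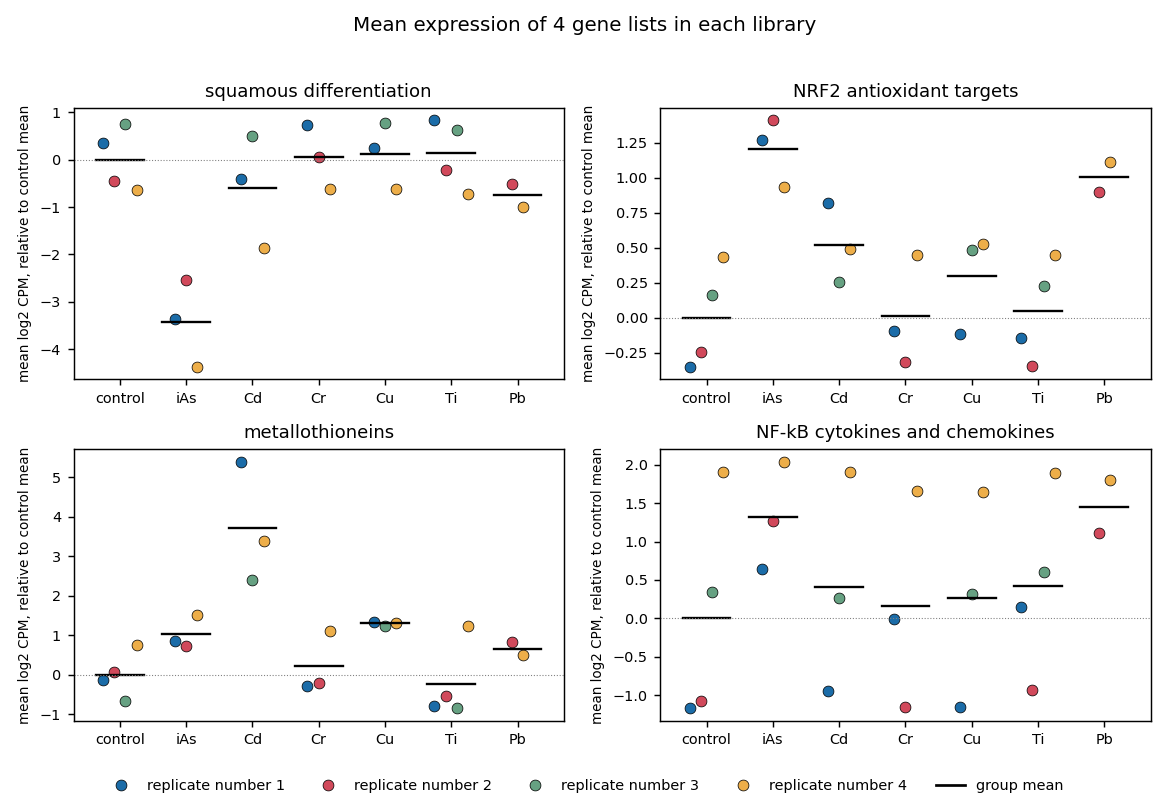
Mean log2 CPM of 4 gene lists in each library, relative to the control mean, by group, with colour for replicate number and a bar for the group mean. The iAs libraries lie at -2.54 to -4.37 for squamous genes, the Cd libraries at 2.39 to 5.40 for metallothioneins, and number-4 libraries lie highest for NF-kB cytokines in each group.

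Arsenic and Cd, at one dose by sample label but not by series text, were compared directly. The squamous genes were lower in iAs than in Cd for 10 of 28 members (20 adjusted over the list alone), as were 4 of 9 metallothioneins (6 adjusted over the list alone). LCE1F, ARSF and ACER1 had 0 counts in iAs, at least 259-fold, 179-fold and 153-fold lower than in Cd. Without Cd 3 these bounds were 76.2-fold, 68.7-fold and 41.7-fold, and without iAs 4 they were 144-fold, 99.5-fold and 85.2-fold. AADACL2 had 2 counts in iAs against 2999 in Cd (964 without Cd 3), and LORICRIN 8 against 7997 (725 without Cd 3). SLC30A1 was 1.56 ± 0.40 lower on the log2 scale (log2 fold change -1.56, adjusted p = 0.0482). Higher in iAs were DHRS2 by 4.06, ABCC2 by 2.99, the plasminogen activator PLAT by 2.13, KCNAB2 by 1.84, RAB17 by 1.67 and the simple-epithelial keratin KRT7 by 1.46. HMOX1 (1.97 ± 0.53, adjusted p = 0.0667), GCLM (1.26), MT2A (-1.37) and MT1X (-1.04) were not called, though HMOX1 passed without Cd 1 (3.25, adjusted p = 0.00298). Without iAs 1 DHRS2 was 2.48 and ABCC2 1.68 higher on the log2 scale, and without Cd 1 they were 5.16 and 4.14 higher. PLAT, ARSF, AADACL2 and LORICRIN passed without each library in turn. KRT7 failed without any library but Cd 4 (adjusted p of 0.0858 to 0.237), ABCC2 without any but Cd 1 (0.0528 to 0.241), SLC30A1 without iAs 2, iAs 4, Cd 1 or Cd 3 (0.109 to 0.272), DHRS2 without iAs 1, iAs 4, Cd 3 or Cd 4 (0.0617 to 0.212), RAB17 without iAs 2, Cd 1 or Cd 3 (0.109 to 0.178), LCE1F without iAs 2, iAs 4 or Cd 3 (0.0568 to 0.0767), KCNAB2 without iAs 1 or Cd 3 (0.0582 and 0.101) and ACER1 without iAs 4 (0.0617).

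By edgeR's quasi-likelihood test 291 genes differed between iAs and Cd, 35 higher and 256 lower in iAs. Camera called the squamous list (median -2.14, adjusted p = 1.03e-22), metallothioneins (-2.45, 7.68e-06) and NRF2 targets (0.56, 2.69e-09, with 2 of 32 higher, and adjusted over the list alone 11 higher and 1 lower), with adjusted p = 0.326, 0.486 and 0.486 with an estimated correlation. Also called were mitotic genes (0.306, 4.79e-05), interferon (0.505, 0.000636), NF-kB cytokines (0.569, 0.00812) and ATF4 stress (0.183, 0.00812). So were DNA replication (0.20, 0.0134) and glycolysis and hypoxia (0.252, 0.0162). None of these further lists held with an estimated correlation (adjusted p of 0.486 to 0.807). The median of the squamous list was -2.79 without iAs 2, and that of metallothioneins -1.55 without Cd 1 and -3.38 without iAs 4. The count was 68 without iAs 4, 80 without Cd 3, 141 without iAs 2, 184 without Cd 1 and 561 without Cd 4, 0 with only the 2 groups in the fit, 95 without iAs 2 and Pb 2, and 752 by DESeq2.

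Copper, Cr and Ti were each compared with control. In Cu, HMOX1 was at 171 ± 28.7 CPM (SD, n = 3) against 59.4 ± 12.5 in control, above control in each of numbers 1, 3 and 4 by 1.32, 1.42 and 1.65 on the log2 scale, but it did not pass (log2 fold change 1.53 ± 0.48, adjusted p = 1). MT1G was at 8.63 ± 6.33 CPM against 0.996 ± 0.683 and MT1H had 41 counts against 3, while MT2A was at 460 ± 309 against 413 ± 257 CPM. None of the 9 metallothioneins passed, 3 did adjusted over the list alone, and camera called the list (median 0.85, adjusted p = 7.56e-08; adjusted p = 0.461 with an estimated correlation). Its mean in Cu minus control was 1.48, 1.91 and 0.58 within numbers 1, 3 and 4. NRF2 targets had a median of 0.23 (adjusted p = 7.35e-06, and adjusted p = 0.725 with an estimated correlation), and were not called without control 1 or Cu 3 (adjusted p = 0.142 and 0.0757). The NRF2 list mean in Cu minus control was 0.23, 0.32 and 0.09 within numbers 1, 3 and 4. Camera at the preset correlation also called nuclear genes of oxidative phosphorylation (0.197, 0.000222), cholesterol synthesis (0.173, 0.000842) and ribosomal proteins (0.118, 0.003). Heat shock targets (0.128, 0.0224), autophagy (0.0809, 0.0224), mitotic genes (-0.11, 0.0233) and mesenchymal genes (-0.287, 0.0393) were called too. None of these further lists held with an estimated correlation (adjusted p = 0.725 for each). MT2A was below control without control 1 (log2 fold change -0.06) or Cu 4 (-0.55).

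In Cr, HMOX1 was at 58.2 ± 19.7 and MT2A at 428 ± 376 CPM, and in Ti at 66.4 ± 30.7 and 382 ± 332 CPM, against 59.4 ± 12.5 and 413 ± 257 in control, and none was called. Their directions turned with single libraries left out, such as MT2A in Cr without Cr 4 (log2 fold change -0.96) and in Ti without control 4 (0.41). In Cr, ribosomal proteins alone were called (median 0.09, adjusted p = 0.00162, and adjusted p = 0.977 with an estimated correlation), with a mean in Cr minus control of 0.25, 0.33 and 0.05 within numbers 1, 2 and 4. With the replicate block their median was 0.18 (adjusted p = 3.21e-17, and adjusted p = 0.479 with an estimated correlation). In Ti the called lists included basal epithelium (-0.23, 0.00254), NF-kB cytokines (0.28, 0.00376) and ribosomal proteins (-0.10, 0.00254). For these 3 lists in Ti the adjusted p was 0.807 with an estimated correlation. Within numbers 1, 2, 3 and 4 the mean in Ti minus control was 1.32, 0.14, 0.25 and -0.0046 for NF-kB cytokines, -0.19, 0.04, -0.26 and 0.01 for ribosomal proteins and -0.47, -0.07, -0.20 and -0.14 for basal epithelium. With the replicate block the NF-kB median was 0.52 (adjusted p = 2.27e-06, and adjusted p = 0.654 with an estimated correlation). Leaving out 1 library leaves its number unpaired, and the number-4 libraries scored highest for NF-kB cytokines in each group. NF-kB cytokines in Ti were at -0.53 without Ti 4 and 1.01 without control 4 and not called without control 1 or 2, ribosomal proteins were at 0.02 without control 3 and 0.01 without Ti 1 and not called without control 4, and basal epithelium was not called without control 1, control 4, Ti 1 or Ti 3. Ribosomal proteins in Cr were not called without control 1, control 2 or Cr 2 (adjusted p of 0.261 to 0.943). With the replicate block, camera called 10 more lists in Cr, among them squamous differentiation (median 0.29, adjusted p = 5.41e-06) and basal epithelium (-0.21, 1.79e-05), with adjusted p = 0.518 and 0.27 with an estimated correlation, and 5 more in Ti, among them squamous differentiation (0.14, adjusted p = 0.0406, and adjusted p = 0.736 with an estimated correlation). By edgeR's quasi-likelihood test 0 genes passed for Cu, Cr or Ti, with 109, 36 and 51 at an unadjusted p under 0.05, and 0 passed in each by DESeq2 and with the replicate block.

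Lead had 2 libraries. NRF2 targets lay above control: none of 32 passed over all genes, 21 did adjusted over the list alone, and camera called the list (median 0.75, adjusted p = 1.76e-32; adjusted p = 0.0649 with an estimated correlation). TXNRD1 was at 601 ± 128 CPM (SD, n = 2) against 219 ± 70.7, GCLC at 725 ± 240 against 227 ± 91.6, GCLM at 80.1 ± 17.4 against 27 ± 10.9 and UGDH at 61.8 ± 7.38 against 36.3 ± 1.43 CPM. NQO1, SQSTM1, MAFG and FTL were at 1.86, 1.97, 1.49 and 2.33 times control, while HMOX1 was at 81.5 ± 24.5 and MT2A at 889 ± 152 CPM. The gene with the smallest adjusted p was CES1, at 64.1 ± 11 against 3.83 ± 3.32 CPM (log2 fold change 4.08 ± 0.70, adjusted p = 0.218). PLIN2, which coats lipid droplets, was at 69.6 ± 15.1 against 24.2 ± 8.79 CPM. The squamous list had a median of -0.97 (adjusted p = 2.23e-05, and 0.628 with an estimated correlation), with KRT1 at 2450 ± 1430 CPM, and NF-kB cytokines 0.72 (adjusted p = 1.07e-06, and 0.628). Within numbers 2 and 4 the NRF2 list mean of Pb minus control was 1.14 and 0.68, and that of the squamous list -0.05 and -0.35. That of NF-kB cytokines was 2.19 and -0.10, with 24 and 9 of 26 members above control, and their median was 1.70 without control 4. Deviations of Pb 2 and control 2 from their group means correlated at -0.0844, so the number-2 differences may also hold a run difference. Camera at the preset correlation also called mitotic genes (0.288, 8.21e-05), cholesterol synthesis (-0.253, 0.000376), heat shock targets (0.277, 0.000735) and oxidative phosphorylation (0.199, 0.000735). ATF4 stress (0.266, 0.0025), iron handling (0.188, 0.0187), metallothioneins (0.774, 0.0447), histones (-0.585, 0.0447) and ribosomal proteins (-0.137, 0.0496) were called too. None of these further lists held with an estimated correlation (adjusted p of 0.45 to 0.694). By edgeR's quasi-likelihood test 0 genes passed, with 735 at an unadjusted p under 0.05 and 1 by DESeq2.

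**Figure D3:**
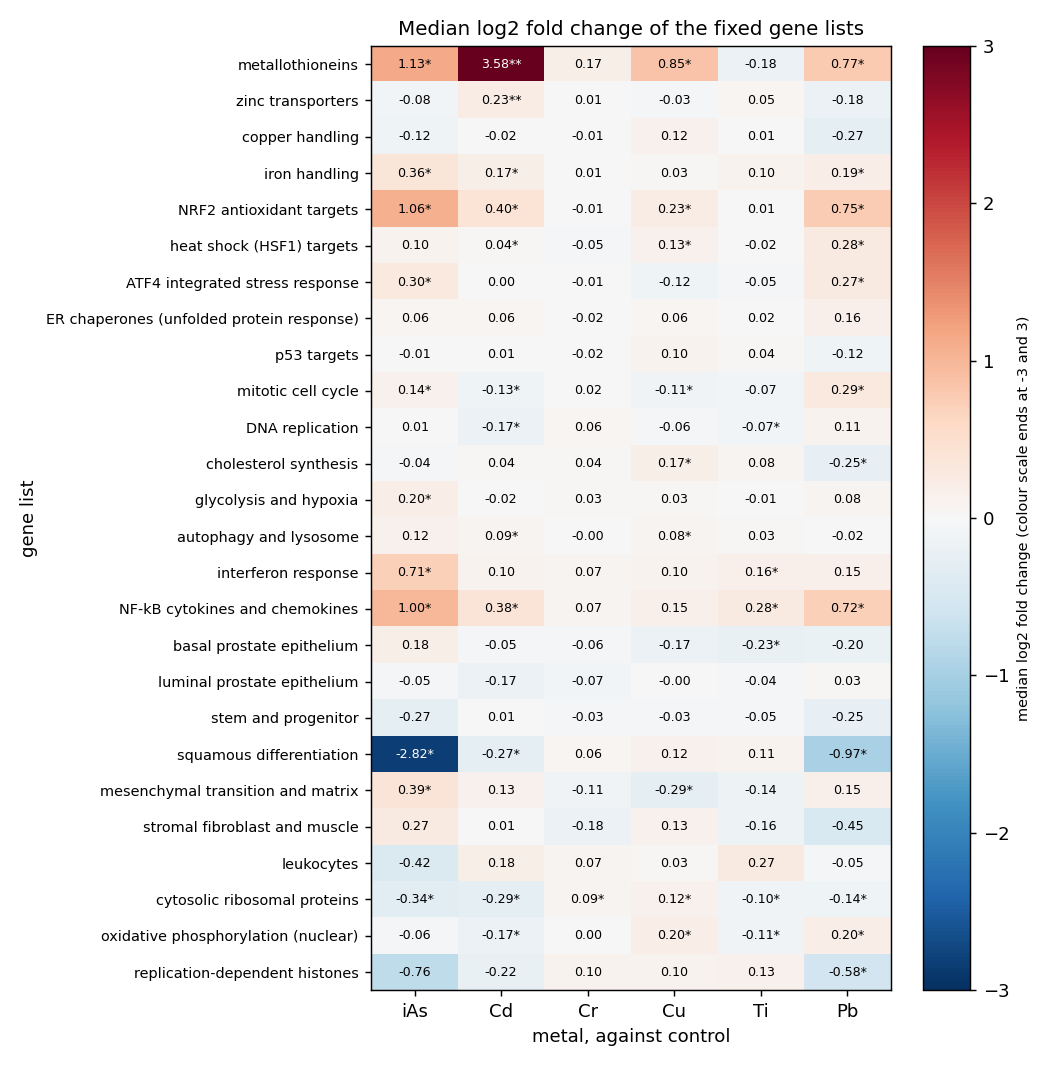
Median log2 fold change of 26 gene lists (rows) for each metal against control (columns), by colour and number. A star marks a list called by camera at the preset correlation and 2 stars one that held with an estimated correlation, which were metallothioneins (3.58) and zinc transporters (0.23) in Cd.

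Other pairs of metals were tested in the same fit. Against iAs, 485 genes differed in Cr, 546 in Cu, 741 in Ti and 33 in Pb, the last all lower in iAs. Cd differed from Ti in 2 genes and Cu from Pb in 1. The other 8 pairs had 0 by edgeR's quasi-likelihood test, with 67 to 1111 genes at an unadjusted p under 0.05. With the replicate number as a block, 113 genes differed between Cd and Cr, 43 between Cd and Cu and 16 between Cd and Ti, and 0 in each pair of Cr, Cu and Ti. Whether the numbers pair these groups was checked against control and not between the metals.

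Of the 164 genes higher in iAs than control, 90.2% lay above control in Pb, 86.6% in Cd, 74.4% in Cu, 58.5% in Ti and 54.3% in Cr. Of the 432 lower genes, 89.1% lay below control in Pb, 76.2% in Cd, 59.5% in Cr, 41% in Cu and 29.2% in Ti. These shares have the control libraries in common. In 10 simulated draws where iAs alone had an effect, the mean share of higher genes was 67.4% to 72.7% without run differences and 69.4% to 73.3% with them. For lower genes it was 62.7% to 63.7% without run differences, and with them 85.9% in Pb, 51.1% in Cd, 79.9% in Cr, 52.7% in Cu and 60.5% in Ti. The draws called more iAs genes than the 164 and 432 in the data. Their means were 605 higher and 955 lower without run differences, and 316 and 614 with them. The simulated and observed shares are thus over unlike sets of genes. With the controls split between iAs and the other metal, genes were called again in each of 6 splits. The share of higher genes over all splits was then 74.1% in Pb, 67.7% in Cd, 37.4% in Cu, 25.5% in Ti and 19% in Cr. That of lower genes was 79.4%, 45.3%, 24.3%, 20.1% and 27.9%. In a split, the controls of iAs and those of the other metal lie on opposite sides of the control mean for each gene. This tends to lower the share, and no share without a common response was simulated for the splits. Low shares therefore do not show that arsenic's genes move the other way in Cr, Cu or Ti. For lower genes in Cr the share was 7.63% with controls 1 and 3 for iAs, and 76.5% with controls 2 and 4. Single splits differed widely, with 7 to 94 higher and 98 to 472 lower genes called. Their shares of higher genes ran from 53.3% to 100% in Pb and in Cd, and 27.1% to 77.8% in Cu. In Ti they ran from 14.6% to 85.7% and in Cr from 12.5% to 42.9%. Shares of lower genes ran from 71.9% to 91.7% in Pb, 19.9% to 84.7% in Cd and 8.9% to 80.6% in Cu. In Ti they ran from 6.14% to 78.6% and in Cr from 7.63% to 76.5%.

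Across genes, which are not independent replicates, the log2 fold changes of iAs and Pb correlated at 0.50, against 0.383 for simulated unchanged groups with the same controls and 0.439 where the simulation kept run differences. Their covariance was 0.273 against 0.104 and 0.0924 simulated, and the correlation was 0.282 with the controls split between the metals. For iAs and Cd the correlation was 0.371 against 0.435 without and 0.351 with run differences, and the covariance 0.144 against 0.104 and 0.0579. For Cd and Pb the covariance was 0.0905, below the 0.104 simulated without run differences and above the 0.0525 simulated with them. In the other 12 pairs the covariance lay below both. These include pairs in which neither metal had a called gene, such as Cr and Cu at 0.0507 against 0.104 and 0.0578. The simulated values are therefore a weak yardstick for the pairs above. No overlap of called genes could be given for Cr, Cu, Ti and Pb, which had 0. For iAs and Cd, 0 higher genes were shared where independent lists would share 0.0301.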

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

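Except for those of iAs 2 and Pb 2 and of the share of iAs 1 RNA in Cd 1, the tests here were chosen after the results were seen. In the groups of 4, control and Ti, 196 values were examined for a library far from the other 3, and 18 stood out, where chance gives about 1 in 20. LINC00324 was added to the genes examined by name, and the values are not independent, so the 18 are no fair count against chance. Control 4 stood apart for FTH1 (2720 CPM, others 852 to 1150), PANX2 (3.70, others 0.214 to 0.724), E2F1 (83.2, others 100 to 102), DNAJB4 (36.3, others 17.9 to 18.4) and LINC00324 (33.3, others 1.82 to 2.76). Control 3 did for LORICRIN (574 CPM, others 79.9 to 128), CRNN (69.2) and ARSF (12.0), and control 1 for MT1H (0.109, others 0). Ti 4 stood apart for the metallothionein score (1.24), the interferon score (0.506), GCLM (45.1 CPM), FTH1 (3090), MT1F (7.91) and MT1H (0.0335). Ti 1 did for HMOX1 (112 CPM, others 45.2 to 54.2), and Ti 3 for PLAT (5.72) and ARSF (12.4).

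The fall of squamous genes in iAs was weighed against technical explanations. A difference between culture runs is argued against by the list scores: the highest iAs score was -2.54, while the 14 control, Cr, Cu and Ti libraries ranged from -0.724 to 0.833. Over all libraries but iAs the lowest score was -1.87, in Cd 4. The argument is weaker for iAs 2, which scored -2.54 and whose run is unresolved. RNA of other cell types would dilute basal epithelial genes as well, but the basal list had a median log2 fold change of 0.176 (median SE of members 0.328). Without each iAs library in turn the list median stayed at -2.42 or lower, so one library does not account for it. That arsenic itself changes which cells are present or what each cell transcribes stays open as a hypothesis, and these data cannot separate these.

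Cd 1 responded more than Cd 3 and Cd 4, with a metallothionein score 2.00 above the higher of them. A culture run 1 with high metallothioneins is argued against, since number-1 control, Cr, Cu and Ti libraries lay at -0.315 relative to the other numbers (SD 0.866). RNA of the iAs 1 library in Cd 1 cannot raise metallothioneins, because iAs 1 itself scored 0.858, below Cd 3 at 2.39 and Cd 4 at 3.40. For genes that respond to iAs this remains open: the share of iAs 1 RNA worked out from 19 rising genes was 27.8% and from 168 falling genes 42.8%, a difference of -15.0 points against 25.6 in Cr 1, 4.39 in Cu 1 and 56.4 in Ti 1, opposite in sign but smaller in size than those of Cr 1 and Ti 1. In Cr 1, Cu 1 and Ti 1 the shares were 1.13%, 1.43% and 5.63% from rising genes. From falling genes they were -24.5%, -2.95% and -50.7%. A share below 0 cannot come from mixed RNA, so these differences are a weak yardstick. More cadmium reaching the cells of Cd 1 is untested.

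The profiles of iAs 2 and Pb 2 matched number 3 and number 1 better than number 2. On 2338 genes with little sign of an iAs or Pb effect, iAs 2 correlated at -0.0572 with the number-2 profile and Pb 2 at 0.287, where Cr 2 and Ti 2 reached 0.439 and 0.493. With the number-3 profile iAs 2 and Pb 2 correlated at 0.0399 and 0.372, each above its value for number 2, where Cr 2 and Ti 2 were at -0.0105 and 0.0227. The number-1 profile was not tested on these genes. Pb 2 was set against Pb 4 alone, and the others against numbers 1 and 4 of their metal. Another culture run, or a metal response hiding the run, cannot be told apart for iAs 2 and Pb 2, because the pair gave values on both sides of the limits set beforehand.

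Other splits of the same libraries test whether chance could give the counts. For iAs against control, 1 of 35 splits, the real one, gave 596 genes or more and the highest other gave 1. These splits disregard the replicate numbers, though iAs and control libraries correlated at 0.341 and 0.285 in numbers 1 and 4 (-0.0861 in number 2). Splits that part all 3 shared numbers, as the real one does, are too few for a share under 0.05, so chance is not excluded. For Cd, 1 of 35 splits, the real one, gave 3 genes or more and the highest other gave 0, but these splits disregard the pairing. The 7 other splits that part all 3 shared numbers also gave 0, and they are too few for a share under 0.05. For Cr, Cu and Ti all 35 splits gave 0, the real one included. Where the real count is 0, every split gives at least as many, so nothing is learned about chance. For iAs against Cd, the 10 splits are too few for a share under 0.05, with 291 genes in the real split and 0 in the highest other.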

How the results depend on the processing

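The settings without iAs 2 and Pb 2 were chosen after seeing the data, the others before. Over 744 checks of 54 called named genes, 570 kept direction and side of the threshold, 174 were no longer past it and 0 reversed. Of the 174, 30 fell short with only the 2 groups in the fit and 26 without iAs 2 and Pb 2.

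The cause was not tested for any of these counts. For iAs against control (596 genes), the count was 2784 with the replicate block, 306 with only the 2 groups, 1194 with DESeq2, 2429 with the block and without iAs 2 and Pb 2, and 213 without these and no block. Leaving out 1 library gave 267 to 625. For Cd (3), it was 15 with the block, 0 with only the 2 groups, 6 with DESeq2, 36 and 1 in the settings without iAs 2 and Pb 2, and 0 to 4 leaving out 1 library. For Pb (0), it was 22 with the block, 1 with DESeq2 and 3 with the block and without iAs 2 and Pb 2, where the lone Pb library is assumed to vary like the others. For iAs against Cd (291), it was 2034 with the block, 0 with only the 2 groups, 752 with DESeq2, 1943 and 95 in the settings without iAs 2 and Pb 2, and 68 to 561 leaving out 1 library. Cr, Cu and Ti had 0 throughout. Between metals, where pairing was not checked except for iAs and Cd, the block gave 3403 genes for iAs and Cr, 2522 for iAs and Cu, 3072 for iAs and Ti, 1047 for iAs and Pb, 69 for Cd and Pb, 111 for Cr and Pb, 42 for Cu and Pb and 48 for Ti and Pb. With DESeq2's size factors or no filter every count stayed within 1.5 times.

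The rule for pairing needs at least 3 shared numbers, each with a correlation over 0.1. By it the replicate numbers do not pair iAs, Pb or iAs and Cd. Same-numbered correlations were -0.0861 to 0.341 over 3 pairs, -0.0844 and 0.239 over 2, and 0.246 to 0.306 over 2. Against control, iAs fell short by number 2 alone, with 0.341 and 0.285 in numbers 1 and 4. For iAs and Cd only the number of pairs fell short. Of 22 libraries, 20 matched their own number best, and iAs 2 and Pb 2 did not, a hint from the data and not the design. In the paired comparisons the block changed list calls at the preset correlation (gained and lost: Cd 1 and 4, Cr 10 and 0, Cu 1 and 2, Ti 5 and 0) and none with an estimated correlation. In the others it gained 1 and lost 2 in iAs (metallothioneins and mitotic genes), gained 1 and lost 4 in Pb, histones among them (median -0.04, adjusted p = 0.915), and gained 2 and lost 1 in iAs against Cd. With the block, the squamous list in iAs and in iAs against Cd held with an estimated correlation (adjusted p = 0.0194 and 0.0418).

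Direction reversed for 5 uncalled genes, in 10 pairings of gene and comparison, and for 3 lists called at the preset correlation, and the cause was not tested. With the block, MKI67 and TP63 in Cd were at 0.04 and 0.06 and MT2A in Cr at -0.241, and with the block and without iAs 2 and Pb 2 at 0.045, 0.122 and -0.242. In the last setting KRT5 in iAs was at -0.149, and at -0.039 without the block. Leaving out 1 library gave -0.047 to 0.36 for KRT5 in iAs, -0.21 to 0.076 for MKI67 in iAs, -0.199 to 0.034 for KRT5 in Cd, -0.311 to 0.184 for MKI67 in Cd, -0.317 to 0.051 for TP63 in Cd, -0.334 to 0.139 for HMOX1 in Cr. It also gave -0.959 to 0.579 for MT2A in Cr, -0.551 to 0.681 for MT2A in Cu, -0.215 to 0.303 for HMOX1 in Ti, -0.913 to 0.413 for MT2A in Ti, -0.704 to 0.163 for squamous differentiation in Cd, -0.185 to 0.0179 for cytosolic ribosomal proteins in Ti, -0.527 to 1.01 for NF-kB cytokines and chemokines in Ti.

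With the controls split between the 2 metals, the correlation was 0.102 for iAs and Cd, -0.102 for iAs and Cr, -0.0941 for iAs and Cu, -0.13 for iAs and Ti, 0.282 for iAs and Pb, -0.201 for Cd and Cr, -0.152 for Cd and Cu, -0.17 for Cd and Ti, -0.0025 for Cd and Pb, -0.192 for Cr and Cu, -0.237 for Cr and Ti, -0.144 for Cr and Pb, -0.175 for Cu and Ti, -0.14 for Cu and Pb and -0.161 for Ti and Pb. In a split, the controls of one metal and those of the other lie on opposite sides of the control mean for each gene. This lowers the value in every pair, so a value below 0 does not show opposite responses. With the split, the covariance went from 0.144 to 0.0491 for iAs and Cd and from 0.0507 to -0.0443 for Cr and Cu. It was lower with the split in every other pair as well.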

Other observations

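Other cell types were looked for with lists fixed before the data were examined. In iAs, 8 tested stromal and muscle genes had a median log2 fold change of 0.27 and 6 leukocyte genes -0.42, with none passing. The list of replication-dependent histones had a median of -0.76 in iAs (camera adjusted p = 0.0981) and -0.58 in Pb (adjusted p = 0.0447, and 0.634 with an estimated correlation). Within numbers 2 and 4 the histone list mean of Pb minus control was 0.41 and -0.44, though Pb 2 did not match the other number-2 libraries best. Heat shock targets had a median of 0.10 and a mean of -0.01 in iAs (adjusted p = 0.584) and 0.28 in Pb (adjusted p = 0.000735, and 0.628 with an estimated correlation).

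Differences between replicate numbers were as large as many metal effects. The NF-kB cytokine score of number-4 libraries lay at 1.64 to 2.04 in every group, arsenic included, while control 1 and control 2 lay at -1.17 and -1.08. The cardiac myosin gene MYH7 was at 1.61 CPM in control 3 and 1.04 CPM in Pb 2, against 0.421 CPM or less in the other libraries.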
